A study of Danio rerio with 4 samples.

How the data were processed

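RNA levels were measured in zebrafish embryos at 12 hours post-fertilization (hpf) with 4 one-colour Agilent expression arrays, 1 for each of 4 groups. Per the labels' protocols, embryos were injected with 4 ng of a control morpholino (MO), 4 ng of an arrb1 MO, 4 ng of an arrb2 MO, or 4 ng of each of the arrb1 and arrb2 MOs, which came to 8 ng in all. A morpholino is an antisense oligomer that blocks translation or splicing of a transcript, and the labels do not say which kind was used. The design text gives 50 embryos without saying whether this number was per group. Total RNA was extracted and carried through the Agilent one-color protocol version 5.5, per the labels' protocols.

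The deposited files hold fluorescence intensity per spot, written by Agilent Feature Extraction version 9.5.1.1, per the file headers. The processed signal in them is an intensity that was background-subtracted and detrended within each array by that program, with low values replaced by surrogates, per the file headers, and no normalization between arrays was applied to it. The headers place all 4 arrays on 1 slide and in 1 scan. The array held 42990 non-control spots for 21495 probes, with 2 spots per probe.

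From these values, log2 of the processed signal minus the 75th percentile of the non-control spots of the same array was computed. Spots marked as outliers by the scanner software were removed, and the remaining spots of a probe were averaged. Probes were kept where every spot was well above background on all 4 arrays, which left 14244 probes. Probes of a gene were averaged on the log2 scale, which gave 11737 genes, 5614 of them with a gene symbol. In all, 10302 probes were named from a table of gene names made for assembly GRCz12tu (7342 by accession, 610 by current symbol and 2350 by older symbol), and 11193 kept the name in the file. Among the 1952 genes with more than 1 measured probe, probes pointed both ways for 302 genes with arrb1 MO against control MO, 403 with arrb2 MO against control MO, 325 with both MOs against control MO and 296 with arrb1 MO against arrb2 MO. Probe positions are those in the files, on build danRer2 per the file headers.

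With 1 array per group no spread within a group exists, so the comparisons give log2 ratios without a test, and a gene is counted where the ratio is at least 2-fold. Genes without a probe measured on all 4 arrays, but well above background on one array of a comparison and with no spot well above background on the other, were counted apart, with a lower bound on the fold. The bound sets the bright value against the higher of the dim probe's own signal and the lowest signal well above background on that array. The SE between spots given beside a ratio comes from repeated spots of probes on the same array, pooled over probes in 20 bins of mean level over the 4 arrays. It is therefore not the spread of the gene's own spots. It covers neither embryos nor RNA preparation, and the number of arrays limits the precision. Each of the 3 injections was compared with control MO, and arrb1 MO was compared with arrb2 MO. The difference made by each MO was also compared between pairs of arrays that share no array, and the departure from additivity was the combined injection minus both single injections plus control. For comparisons that share the control array, 100 sets of unchanged groups were simulated from the spot noise.

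A total of 37 gene lists were fixed. They covered arrestin genes, caudal genes, hox genes of paralog groups 1 to 4, 5 to 8 and 9 to 13, blood and endothelial progenitor, primitive erythroid, myeloid, pronephros and intermediate mesoderm, heart field, presomitic mesoderm and segmentation, muscle, tailbud, notochord and floor plate, neural plate regional, pan-neural progenitor, neuronal differentiation, neural crest, endoderm and pharyngeal, epidermis and enveloping layer, hatching gland, yolk syncytial layer, germ cell, blastula and gastrula, p53 response, interferon and innate immune, Polycomb and YY1, Wnt, Fgf, Hedgehog, Notch and Bmp pathway target, retinoic acid pathway, cell cycle, ribosomal protein, heat shock and unfolded protein genes, and G protein-coupled receptor signalling regulators. The lists overlap: 82 of their 632 measured genes sit in more than 1 list. The median log2 ratio of a list was set against 10000 random lists of the same size, matched on mean level in 20 bins. A list is said to stand apart where its median lies under the 2.5th or over the 97.5th percentile of its random lists, as a description of these arrays, and lists with under 5 measured genes are given as values. The caudal, hox, blood and endothelial progenitor and primitive erythroid lists were the 6 primary lists.

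Genes are named by a rule: the arrestin targets, the 10 highest and 10 lowest genes with a symbol whose probes all pointed one way, up to 4 members with the largest ratio in each primary list and each list that stood apart, a set of fixed blood and hox genes, up to 3 genes each way with the largest bound, and up to 10 genes per direction at least 2-fold the same way in both pairs that share no array. The text gives some of them by group. For arrb1 MO against arrb2 MO the 5 highest and 5 lowest were taken. The lists, this rule, the comparisons and 7 alternatives were chosen before the data were examined. The alternatives were quantile normalization, scaling to the median, cyclic loess, normexp background correction with an offset of 50, no filter on dim probes, only the brighter probes, and the brightest probe of each gene. After the data were seen, an additive model was also fitted to the 4 arrays with lmFit and eBayes of limma 3.58.1. It had 3 coefficients (mean, arrb1 MO and arrb2 MO) and 1 residual degree of freedom per gene, to which eBayes added 3.02 prior degrees of freedom, with two-sided p-values adjusted by Benjamini-Hochberg over 11737 genes for each MO. Each MO effect in it is the mean of the log2 ratios without and with the other MO. An interaction of the MOs, which coincides with the effect of total dose, therefore enters both effects as well as the residual. The fit was not tested on simulated data. A pair of further lists, of adult eye genes and of other egg genes, was added afterwards for the closing section.

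The steps were tested on simulated data for arrb1 MO against control MO with 11737 genes and spot noise alone. All 66 genes made 3-fold different and all 66 made 4-fold different passed the 2-fold threshold, as did 2 of 68 made 1.5-fold different and 1 of 11517 unchanged genes. Background correction by normexp, cyclic loess and quantile normalization used limma 3.58.1 in R 4.3.3. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.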

Results

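Messenger RNA was profiled in whole zebrafish embryos at 12 hpf after injection of control MO, arrb1 MO, arrb2 MO, or both arrestin MOs. Beta-arrestins, the products of arrb1 and arrb2, are adaptor proteins of G protein-coupled receptors, and the series was made to find genes that differ when they are depleted. Each group had 1 array, so no group had replicates and the number of arrays limits the precision. Each MO could be compared on a second pair of arrays only through the combined injection. Spots well above background made up 69.8% of the control MO array, 70.9% of the arrb1 MO array, 72.7% of the arrb2 MO array and 72.7% of the array for both MOs. The median SE between spots of a log2 ratio was 0.08 for arrb1 MO, 0.08 for arrb2 MO and 0.08 for both MOs against control MO. Across 140 combinations of list and comparison, 59 list medians stood apart from their random lists, against 7 for lists of randomly drawn genes. Members of a list can vary together, lists share genes and comparisons share arrays. The 7 therefore does not cover variation between groups of embryos, and setting 59 against it is no test.

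The arrestin transcripts were examined first. No probe on the array carried the name arrb1, so the first target was not measured under that name. The arrb2a transcript (chromosome 10, 9789810 to 9789869, danRer2) had log2 ratios against control MO of 0.34 with arrb1 MO, −0.06 with arrb2 MO and 0.46 with both. The arrb2b transcript (chromosome 7, 18246943 to 18247002, danRer2) had −0.15 with arrb1 MO, 0.30 with arrb2 MO and −0.61 with both. A morpholino can block translation and leave its transcript in place, so these values check neither the depletion nor the labels. Of the 7 arrestin genes on the fixed list 3 were measured, and the other one, the photoreceptor arrestin arr3b, which the rule for named genes does not take and which was added after its values were seen, had −0.05, 0.47 and 0.77 in the same order.

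The first comparison asks which genes differ when arrb1 is targeted. With arrb1 MO, genes of the blastula and gastrula, which pattern the early embryo, were higher than with control MO, and genes of neuronal differentiation were lower. The 30 measured blastula and gastrula genes had a median log2 ratio of 0.70 (percentile 100), with 7 at least 2-fold higher and 0 lower, among them the yolk layer factor mxtx2 at 2.64 ± 0.17 (SE between spots), the Nodal ligand ndr2 at 1.80 and the endoderm factor sox32 at 1.57. The 26 neuronal differentiation genes had a median of −0.76 (percentile 0), with 9 at least 2-fold lower and 0 higher, among them the proneural gene ascl1a at −1.55, the zinc finger gene scrt2 at −1.52 and the Delta ligand dlb at −1.46. With only the brighter probes that neuronal median was −0.32, and with normexp the ratio was 1.16 for mxtx2, 0.67 for ndr2 and 0.94 for sox32.

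Blood genes were among the lower ones with arrb1 MO. The erythroid transcription factor gata1a (chromosome 11, 21054003 to 21054062, danRer2) had a log2 ratio of −2.19 ± 0.17, which is 4.55-fold lower. The blood and endothelial progenitor genes had a median of −0.52 (percentile 0.01) over 15 measured genes, of which 3 were at least 2-fold lower and 1 higher. The Ets factor gene fli1rs was at −1.65, the Ets factor erg at −1.05 and the stem cell leukemia factor tal1 at −0.99, and the blood cofactor lmo2 was 2.14-fold lower, whereas the zinc finger gene drl was at 1.40. The myeloid factor spi1b was at −1.38 and the progenitor factor myb at −0.56. The spi1b value averages a probe on chromosome 7 (danRer2) at −1.73 and one on chromosome 12 at −1.03. Whether both read the same gene is open. With only the brighter probes the progenitor median was −0.20 and lay inside its random lists (percentile 7.27), and with normexp it was −0.17, with gata1a at −1.33, fli1rs at −0.79, erg at −0.80 and spi1b at −0.43; erg was at −0.98 with quantile normalization. The 15 primitive erythroid genes went both ways, with a median of −0.03 (percentile 41.3; 0.03 with scaling to the median and 0.10 with only the brighter probes), 2 of them at least 2-fold higher and 4 lower. The heme enzyme gene urod was at −1.69, while the red cell anion exchanger slc4a1a (chromosome 3, 9334328 to 9334387, danRer2) was the highest named gene among those measured on all 4 arrays, at 2.93, and the Krüppel-like gene blf was at 1.26.

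**Figure D1:**
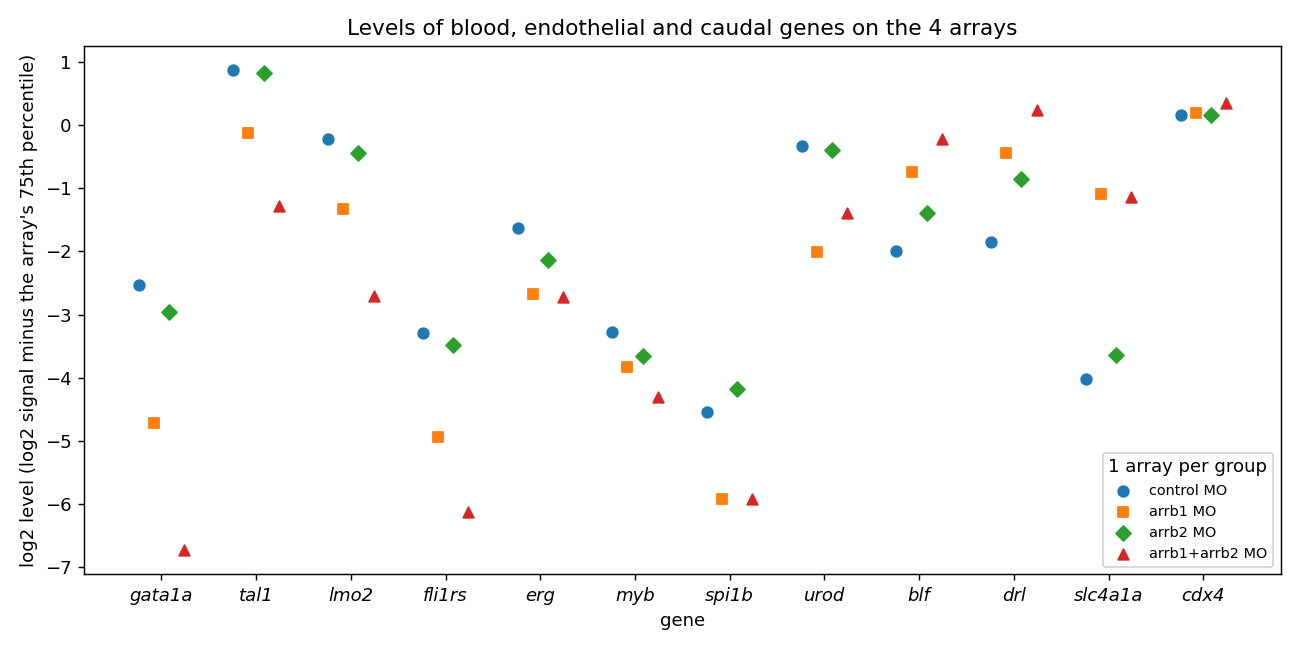
Log2 level (log2 signal minus the 75th percentile of the array) of blood, endothelial and caudal genes on the 4 arrays, 1 point per array. The level of gata1a had a log2 ratio against control MO of −2.19 with arrb1 MO and −4.21 with both MOs, while slc4a1a was higher on both of those arrays.

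The hox genes, which set position along the body axis, were compared in 3 lists. Posterior hox genes of groups 9 to 13 had a median of −0.32 with arrb1 MO (percentile 1.05, 14 measured, 1 at least 2-fold lower), with hoxc11a at −1.49, hoxa10b at −0.88 and hoxd12a at −0.81. With only the brighter probes that median was −0.10 (percentile 26.1), and with normexp it was −0.17 (percentile 1.40), with hoxc11a at −0.64. Groups 1 to 4 had −0.25 (percentile 2.83, 12 measured; −0.11 with normexp, percentile 6.93, and −0.16 with no filter) and groups 5 to 8 had −0.19 (percentile 8.29, 11 measured; −0.12 with quantile normalization), neither with a gene past 2-fold. The caudal factor cdx4, the 1 measured gene of the 3 on the caudal list and a regulator of hox genes, had a log2 ratio of 0.02, with its 4 probes pointing both ways. The blood regulator runx1 and the caudal gene cdx1a were not well above background on any array, and cdx1b had no probe.

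Other tissues also differed with arrb1 MO. Neural plate regional genes had a median of −0.38 (percentile 0; −0.24 with normexp; 6 of 34 at least 2-fold lower), led by the retinal homeobox genes rx1 at −2.75 (−1.18 with normexp) and rx2 at −2.38, and pan-neural progenitor genes had −0.46 (percentile 0; 3 of 19 lower), with zic5 at −1.39. Muscle genes had −0.28 (percentile 0.3; 6 of 29 lower), with the calcium pump atp2a1 at −1.90 (−0.98 with normexp), the caveolin cav3 at −1.17 (−0.66 with normexp) and desmin (desma) at −1.11. Germ cell genes had 0.65 (percentile 100; 1 of 10 higher), with dazl at 2.24 but at 1.24 in the additive fit, which also uses the pair without the control array. Tailbud genes had 0.40 (percentile 100; 0.65 with only the brighter probes; 2 of 18 higher and 1 lower), endoderm and pharyngeal genes 0.36 (percentile 99.96) and Bmp targets 0.42 (percentile 100; 4 of 24 higher), with ved at 1.60, msx2b at 1.45 and bmp4 at 1.17. The tailbud, Bmp target and blastula and gastrula lists share genes, among them ved and vent. Their medians are therefore not independent of each other in any comparison. Genes that respond to p53, the factor that answers DNA damage, had 0.58 (percentile 100; 7 of 19 higher and 1 lower), with gadd45aa at 1.82 and mdm2 at 1.26.

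Smaller shifts with arrb1 MO were seen in 4 more lists. Epidermis and enveloping layer genes had 0.17 (percentile 98.9; 0.06 with no filter on dim probes, percentile 73.0) and heat shock and unfolded protein genes 0.16 (percentile 98.1; 0.07 with the brightest probe, percentile 78.6, among others). The probes named for the chaperone genes hsp70 and hsp70.3 were at 2.72 and 2.66. They lie close together on chromosome 3 (16141123 to 16141182 and 16140984 to 16141043, danRer2), so they may read the same transcript. Near-identical copies can also share probe signal, so these values are not separate evidence. Notch targets had −0.20 (percentile 1.26; −0.10 with only the brighter probes, percentile 12.0, among others) and ribosomal protein genes −0.05 (percentile 0.17; 0.01 at the same percentile with scaling to the median, which shifts all genes alike).

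In all, 212 genes were at least 2-fold higher and 449 lower with arrb1 MO than with control MO. Bounds added 23 higher, led by the glycine receptor gene glra4b at least 13.3-fold higher, and 43 lower, led by the troponin tnnt2c at least 7.68-fold lower. Among the 10 lowest named genes measured on all 4 arrays were the linker histone genes h1-10 at −3.66 and histh1l1 at −3.23, the muscle genes myl13 at −3.35 and ttnl at −3.34, the thymosin gene tmsb at −3.26 and the tubulin tuba8l3 at −2.91. With normexp h1-10 was at −2.31, ttnl at −2.09 and tmsb at −1.30, and ttnl was at −1.76 with no filter. The total of 661 became 298 with normexp, 1271 with no filter and 171 with only the brighter probes.

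**Figure D2:**
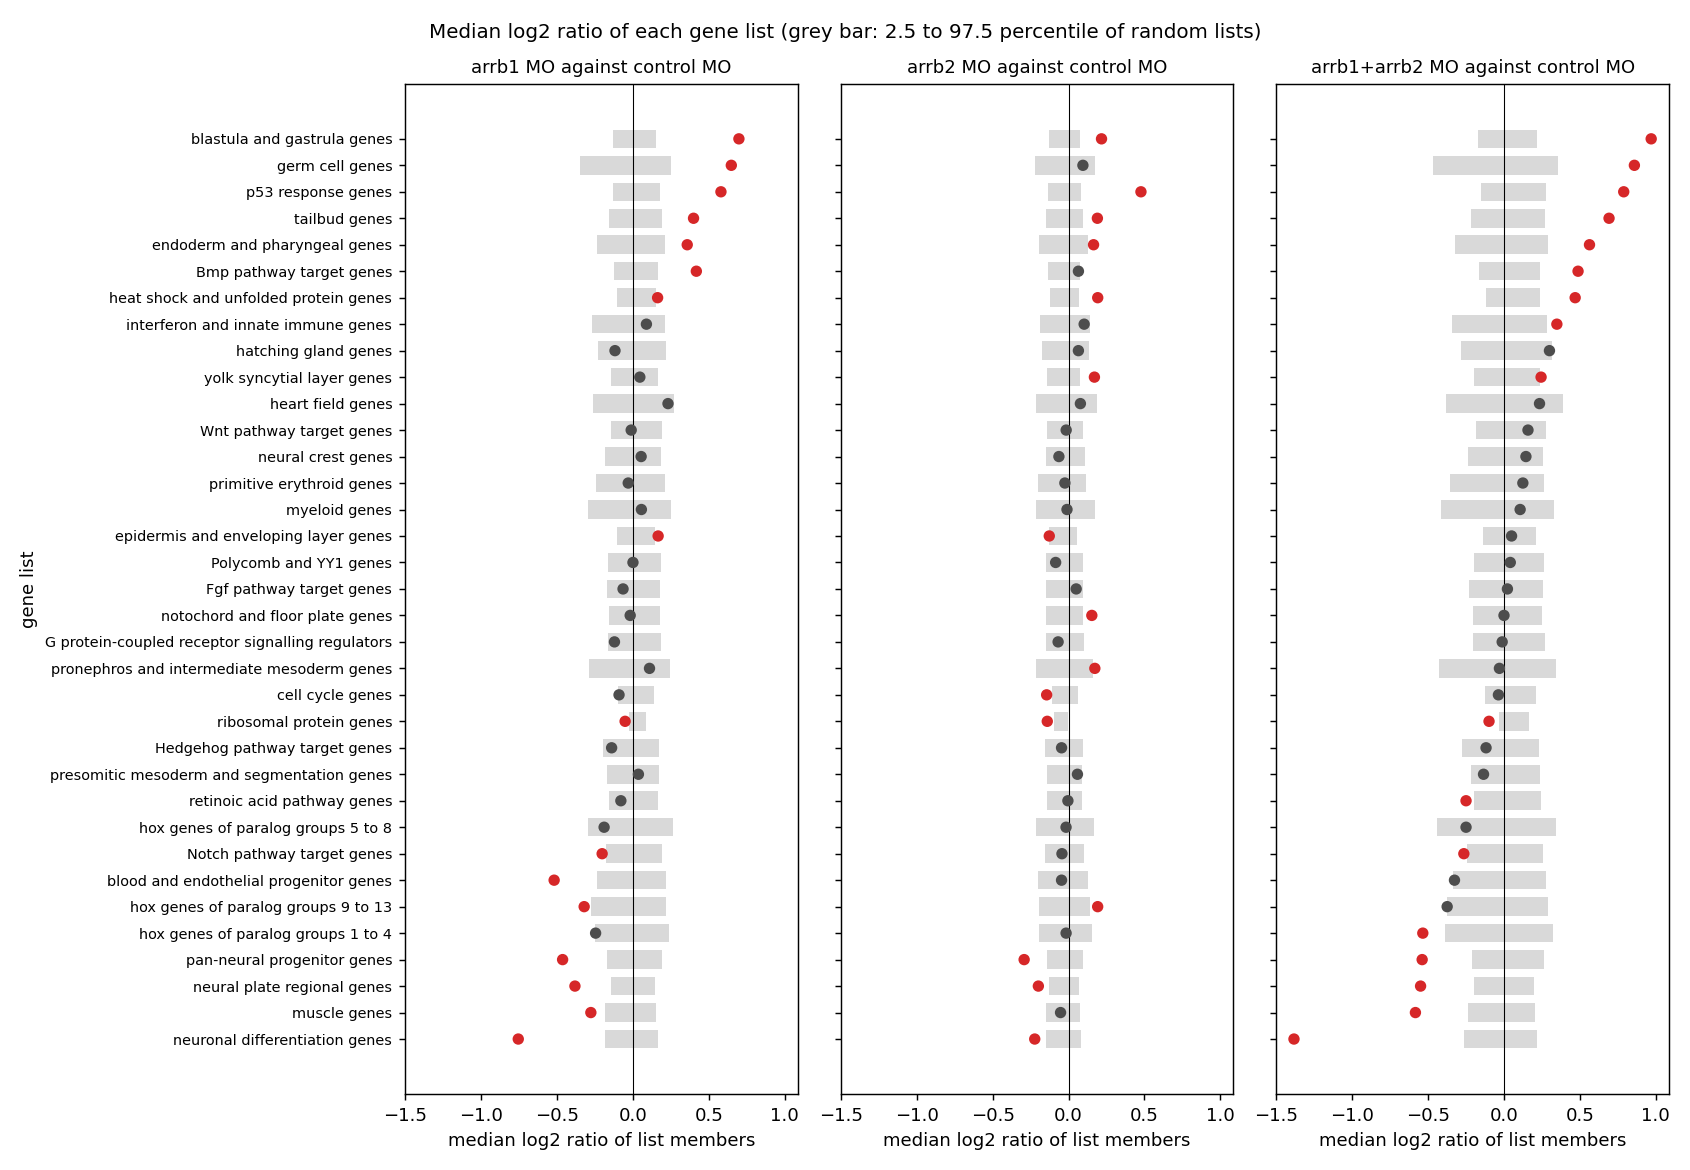
Median log2 ratio of the members of each gene list against control MO (points; red where the list stands apart) with the range of its random lists (grey bars). Neuronal differentiation genes lie lowest with arrb1 MO at −0.76 and with both MOs at −1.38, and blastula and gastrula genes highest at 0.70 and 0.97.

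The second comparison asks the same of arrb2. The arrb2 MO array differed less from control MO, with 135 genes at least 2-fold higher and 82 lower, and blood progenitor genes lay inside their random lists (median −0.05, percentile 44.7). The retinaldehyde-binding gene rlbp1b (chromosome 25, 9376053 to 9376112, danRer2) was highest among genes measured on all 4 arrays, at 6.22 ± 0.07, which is 74.7-fold, followed among named genes by the fetuin ahsg1 at 2.46, the bile acid transporter slc51a at 2.37 and the RNA-binding gene cpeb4a at 2.16. The RNA-binding genes caprin2 at 1.86 and rbpms2b at 1.80 were also higher, while the fucose transporter slc35c1 was at −3.38, the elastase ela2l at −3.26 and the mitochondrial topoisomerase top1mt at −2.41. With normexp ahsg1 was at 1.25, slc51a at 0.74, rbpms2b at 0.98 and ela2l at −1.66.

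The p53 response genes had a median of 0.48 (percentile 100) with arrb2 MO, with 4 of 19 at least 2-fold higher, including casp8 at 1.52 and gadd45aa at 1.45. Blastula and gastrula genes had 0.22 (percentile 99.99; 2 of 30 higher; 0.11 with normexp), with mxtx2 at 1.74, which was 0.53 with normexp. Tailbud genes had 0.19 (percentile 99.9), endoderm and pharyngeal genes 0.17 (percentile 99.1; 0.08 with no filter, percentile 90.5), heat shock and unfolded protein genes 0.19 (percentile 100), yolk syncytial layer genes 0.17 (percentile 99.95; 0.08 with no filter, percentile 96.5) and notochord and floor plate genes 0.15 (percentile 99.8; 0.10 with normexp). Pronephros and intermediate mesoderm genes had 0.17 (percentile 98.2; 0.06 with normexp, percentile 94.6, among others). Posterior hox genes of groups 9 to 13 had 0.19 (percentile 99.3), with hoxd11a at 0.93 and hoxd10a at 0.66 and none past 2-fold. The median of that list was −0.37 with both MOs and −0.32 with arrb1 MO. It therefore did not rise where arrb2 MO was added to arrb1 MO, though with only the brighter probes these values were −0.03 and −0.10.

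Neural lists were lower with arrb2 MO, with neuronal differentiation genes at −0.22 (percentile 0.1), pan-neural progenitor genes at −0.29 (percentile 0) and neural plate regional genes at −0.20 (percentile 0.04), and 0 of their members past 2-fold. The proneural gene ascl1a was at −0.97. Epidermis and enveloping layer genes had −0.13 (percentile 2.35; −0.08 with cyclic loess, percentile 4.11, among others), cell cycle genes −0.14 (percentile 0.22) and ribosomal protein genes −0.14 (percentile 0; −0.03 with quantile normalization, percentile 6.73). The other primary lists lay inside their random lists: hox groups 1 to 4 at −0.02 (percentile 55.4, and 0.01 with cyclic loess), hox groups 5 to 8 at −0.02 (percentile 53.6, and 0.01 with cyclic loess) and primitive erythroid genes at −0.02 (percentile 57.7, and 0.01 with cyclic loess), with gata1a at −0.43, tal1 at −0.05, lmo2 at −0.22 and cdx4 at −0.01 (0.02 with quantile normalization). Bounds added 15 higher, led by the splicing gene smu1a at least 83.6-fold higher, and 6 lower. The total of 217 became 96 with normexp, 664 with no filter, where 52.1% were higher against 62.2%, and 69 with only the brighter probes.

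The third comparison asks what both MOs do together, at a total dose of 8 ng against 4 ng of control MO. With both MOs 544 genes were at least 2-fold higher and 927 lower. With scaling to the median these were 661 and 793, or 45.5% higher against 37.0%. The blood genes gata1a, at −4.21 ± 0.16 (18.4-fold lower), fli1rs at −2.83, lmo2 at −2.48, tal1 at −2.15 and myb at −1.03 had lower ratios than with either MO alone. With normexp gata1a was at −2.19, fli1rs at −1.55 and myb at −0.78, and myb was also under 2-fold with quantile normalization at −0.92, among others. The myeloid factor spi1b was at −1.39 (−0.85 with normexp, −2.10 with the brightest probe), while drl was at 2.08. The spi1b probe on chromosome 7 was at −2.10 and that on chromosome 12 at −0.68. The progenitor list had a median of −0.33 (percentile 2.92), with 6 of 15 at least 2-fold lower and 1 higher. That median depended on the probes used: it was −0.81 (percentile 0.01) with no filter and −0.38 (percentile 1.91) with normexp, but 0.04 (percentile 49.4) with only the brighter probes. The primitive erythroid genes had a median of 0.12 (percentile 83.2), with tspan33a, a tetraspanin, at −2.29 and slc4a1a at 2.89, and that median ran from −0.20 with normexp to 0.33 with only the brighter probes.

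Neuronal differentiation genes had the lowest median of any list with both MOs, −1.38 (percentile 0), with 14 of 26 at least 2-fold lower, including scrt2 at −2.60, nhlh2 at −2.60 and neurod1 at −2.39. With only the brighter probes that median was −0.36 (percentile 1.1). Neural plate regional genes had −0.55 (percentile 0; 10 of 34 lower), pan-neural progenitor genes −0.54 (percentile 0.01; −0.35 with only the brighter probes) and muscle genes −0.58 (percentile 0; 9 of 29 lower and 1 higher), with the muscle regulator myog at −2.73. Anterior hox genes of groups 1 to 4 had −0.54 (percentile 0.58) with none of 12 past 2-fold, groups 5 to 8 had −0.25 (percentile 10.7; −0.15 with scaling to the median and −0.39 with only the brighter probes), with hoxb6a at −1.54, and groups 9 to 13 had −0.37 (percentile 2.63), with 3 of 14 lower. That last median was −0.03 (percentile 38.8) with only the brighter probes, and it stood apart at −0.38 (percentile 2.4) with cyclic loess and at −0.46 (percentile 1.64) with no filter, among others. Retinoic acid pathway genes had −0.25 (percentile 0.94; −0.04 with only the brighter probes, percentile 16.7), Notch targets −0.26 (percentile 1.91; −0.07 with only the brighter probes, percentile 21.6, among others) and ribosomal protein genes −0.10 (percentile 0.01; −0.18 with cyclic loess). The retinoic acid list also holds hox genes, among them hoxb4a, hoxd4a, hoxb5a and hoxb6b, and its median equals that of hox groups 5 to 8. Its shift is therefore not independent of the hox lists.

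Blastula and gastrula genes had the highest median with both MOs, 0.97 (percentile 100), with 14 of 30 at least 2-fold higher and 0 lower, including the Nodal antagonist lft2 at 3.26, ndr2 at 3.17, sox32 at 3.16 and mxtx2 at 3.06, where ndr2 was at 1.42 and mxtx2 at 1.30 with normexp. Germ cell genes had 0.86 (percentile 100; 5 of 10 higher), with nanos3 at 1.53 and ddx4 at 1.40. The p53 response genes had 0.79 (percentile 100; 8 of 19 higher and 1 lower), tailbud genes 0.69 (percentile 100; 6 of 18 higher and 1 lower), Bmp targets 0.49 (percentile 99.99; 6 of 24 higher) and heat shock and unfolded protein genes 0.47 (percentile 100; 4 of 24 higher and 1 lower). Endoderm and pharyngeal genes had 0.56 (percentile 99.96; 0.30 with normexp) and yolk syncytial layer genes 0.24 (percentile 97.8; 0.04 with the brightest probe, percentile 50.5, among others). Interferon and innate immune genes had 0.35 (percentile 99.3), but −0.06 with no filter and −0.06 with only the brighter probes. Among genes measured on all 4 arrays, the highest named gene was rlbp1b at 5.04, followed by the small ribonucleoprotein gene snu13a at 3.26, and the lowest was tuba8l3 at −4.45, with cldn1, a tight junction gene, at −3.40. Bounds added 49 higher and 80 lower, with glra4b at least 17.1-fold higher and the actin-severing gene scinla at least 17.1-fold lower. The total of 1471 became 900 with normexp, 2375 with no filter and 489 with only the brighter probes.

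Comparison of array pairs that share no array asks whether a difference recurs. The second pair of each MO also differs in total dose, 8 ng against 4 ng, so a recurrence there can hold an effect of dose. For arrb1 MO, the log2 ratio against control MO and that of both MOs against arrb2 MO had a correlation across genes of 0.69 (covariance 0.208; genes are not independent replicates). Of genes at least 2-fold in both pairs, 79 were higher and 325 lower in both, against 4.95 and 28.3 for independent lists, and 3 went opposite ways. The retinal genes rx1 (−2.75 and −2.61) and rx2 (−2.38 and −2.90), the muscle genes myl13 (−3.35 and −3.79) and ttnl (−3.34 and −3.43), the organizer gene gsc (1.48 and 1.87) and slc4a1a (2.93 and 2.51) were among them. For arrb2 MO the correlation was 0.39 (covariance 0.0602), with 40 higher and 26 lower in both pairs, against 2.24 and 1.75, and 6 opposite. The egg coat gene zp3b (1.52 and 1.70), the oocyte kinase wee2 (1.66 and 1.32), rbpms2b (1.80 and 2.04) and rlbp1b (6.22 and 3.89) were higher in both. The same-way totals of 404 for arrb1 MO and 66 for arrb2 MO became 178 and 32 with normexp.

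**Figure D3:**
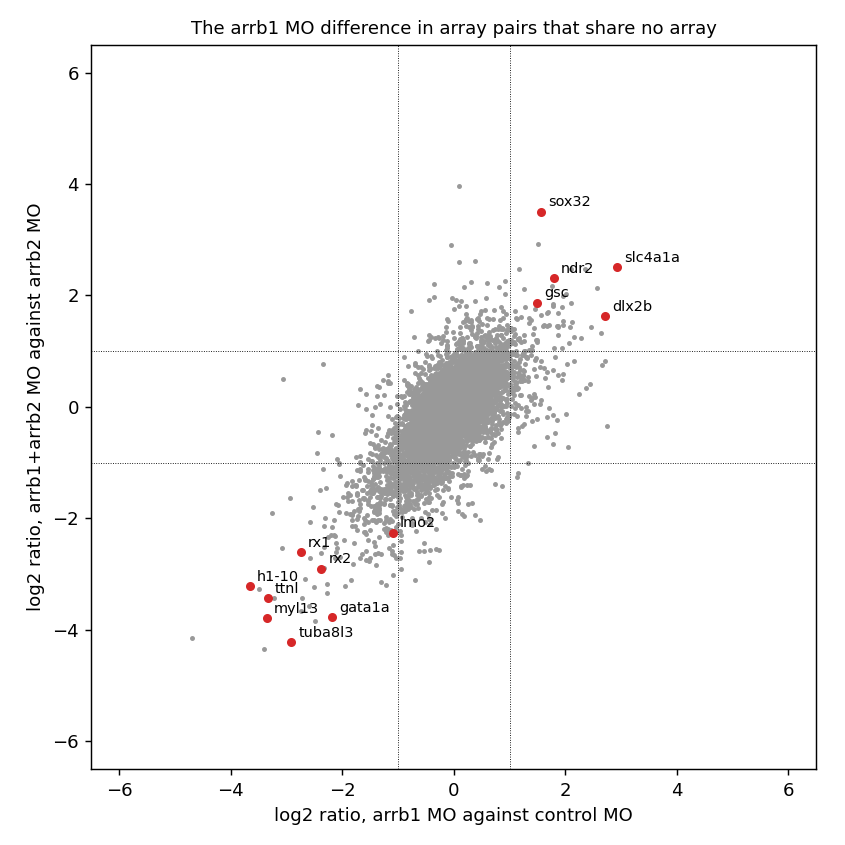
Log2 ratio of each gene for arrb1 MO against control MO (horizontal axis) and for both MOs against arrb2 MO (vertical axis), 1 point per gene, with dotted lines at 2-fold and some genes named in red. The pairs share no array, and rx1 lies at −2.75 and −2.61 and slc4a1a at 2.93 and 2.51.

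Against the shared control array, the arrb1 MO and arrb2 MO differences had a correlation across genes of 0.41 and a covariance of 0.0734. Simulated unchanged groups gave a correlation of 0.59 and a covariance of 0.0104, so the covariance is the value to compare. Together 51 genes were at least 2-fold higher and 24 lower with both single MOs, against 2.44 and 3.14 for independent lists and 0.01 and 0.01 for unchanged groups simulated with spot noise alone, and 3 went opposite ways. The simulation leaves out variation between embryos and RNA preparations, so unchanged groups of embryos could give more. Part of the excess of 51 and 24 may come from the shared control, which could not be split. Among genes 2-fold with each single MO, mxtx2 was at 2.64 and 1.74, cpeb4a at 2.03 and 2.16, casp8, a caspase gene, at 1.56 and 1.52, and slc35c1 at −3.06 and −3.38. In the additive fit, which also uses the pair without the control array, their arrb1 MO effects were smaller in size. They were 1.98 for mxtx2, 1.40 for cpeb4a, 0.84 for casp8 and −1.28 for slc35c1. A deviant value on the control array stays open for such genes, most of all for casp8 and slc35c1.

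An additive fit over the 4 arrays, chosen after the data were seen, tested each MO with limma, with 1 residual degree of freedom, which holds the departure from additivity. The p-values set an effect against that departure and do not cover spread between embryos or RNA preparations. A gene whose difference is stronger with both MOs than additivity gives can miss the threshold for that reason. Each effect is the mean over both pairs of arrays that differ in that MO, the second pair at 8 ng against 4 ng, so it also carries part of that departure and of any effect of dose. For arrb1 MO 117 genes were higher and 343 lower at an adjusted p under 0.05. The muscle gene myl13 (log2 effect −3.57 ± 0.16, SE; adjusted p = 0.0347 in limma), slc4a1a (2.72 ± 0.16; adjusted p = 0.0347 in limma) and gata1a (−2.98 ± 0.41; adjusted p = 0.0497 in limma) passed. The blood genes lmo2 (−1.68 ± 0.31; adjusted p = 0.0709 in limma) and tal1 (−1.55 ± 0.30; adjusted p = 0.0755 in limma) did not. For arrb2 MO 0 genes passed in limma, while 1572 had an unadjusted p under 0.05, and rlbp1b had an effect of 5.06 ± 0.59 (adjusted p = 0.234 in limma). The count for arrb1 MO depended on the setting: it was 275 with quantile normalization, 899 with scaling to the median, 1375 with normexp and 0 with no filter (3463 at an unadjusted p under 0.05), and the count for arrb2 MO was 71 with normexp.

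The departure of the combined injection from the sum of both single injections had a median of 0.03 and an SD of 0.44 across genes, with a median SE between spots of 0.10. It passed 1 in size for 462 genes, 175 above and 287 below, and it holds the noise of all 4 arrays as well as the difference in dose. The sum of both single log2 ratios had a correlation of 0.81 with the combined one across genes. The count of 462 became 188 with normexp, 1464 with no filter and 101 with only the brighter probes.

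The last comparison sets arrb1 MO directly against arrb2 MO. With arrb1 MO 160 genes were at least 2-fold higher and 440 lower than with arrb2 MO. Blood and endothelial progenitor genes had a median of −0.44 (percentile 0.01; 1 of 15 lower; −0.12 with normexp), with fli1rs at −1.46 and tal1 at −0.95, and gata1a was at −1.75, which with normexp were −0.60 for fli1rs and −0.94 for gata1a. Posterior hox genes of groups 9 to 13 had −0.61 (percentile 0), with 4 of 14 at least 2-fold lower, including hoxc11a at −1.49, hoxd11a at −1.31 and hoxa11b at −1.27, which were −0.53, −0.62 and −0.96 with normexp. Hox groups 1 to 4 had −0.21 (percentile 2.99; −0.13 with normexp, percentile 1.55) and groups 5 to 8 had −0.21 (percentile 4.82; −0.10 with no filter and −0.12 with normexp), and primitive erythroid genes had −0.04 (percentile 27.07; 0.03 with scaling to the median and 0.11 with normexp).

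Among other lists of that comparison, Bmp targets had 0.45 (percentile 100; 1 of 24 higher), germ cell genes 0.36 (percentile 99.6), epidermis and enveloping layer genes 0.35 (percentile 100; 1 of 29 higher and 2 lower), with krt91 at 1.42, blastula and gastrula genes 0.29 (percentile 100; 3 of 30 higher) and tailbud genes 0.23 (percentile 99.0; 0.01 with no filter, percentile 32.2). Neuronal differentiation genes had −0.44 (percentile 0; 5 of 26 lower; −0.22 with only the brighter probes), muscle genes −0.33 (percentile 0.02; −0.21 with normexp), neural plate regional genes −0.16 (percentile 0.65; −0.06 with only the brighter probes, percentile 8.84) and notochord and floor plate genes −0.12 (percentile 2.17; −0.07 with no filter, percentile 5.56). The p53 response genes were at 0.15 (percentile 91.2). Among genes measured on all 4 arrays, the highest and lowest named genes were ela2l at 3.06, rlbp1b at −5.07 and tmsb at −3.96, where ela2l was at 1.55 and tmsb at −1.78 with normexp. Bounds added 14 higher and 54 lower, led by smu1a at least 91.9-fold lower. The total of 600 became 261 with normexp, 1151 with no filter and 156 with only the brighter probes. Scaling to the median moved the median of all genes to 0.11 here and to 0.10 for both MOs against control MO, from 0.04 and 0.01.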

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

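The 2 results here drew attention because a gene list moved one way with arrb1 MO and the other way with arrb2 MO, each outside its random lists, and the difference between the MOs was not tested. Hox genes of groups 9 to 13 were lower with arrb1 MO (−0.32) and higher with arrb2 MO (0.19), a difference of −0.61 in the direct comparison, but the arrb1 MO value was −0.10 and inside its random lists with only the brighter probes. With both MOs the median was −0.37, so it did not rise where arrb2 MO was added to arrb1 MO. With only the brighter probes it was −0.03 with both MOs. Epidermis and enveloping layer genes were higher with arrb1 MO (0.17) and lower with arrb2 MO (−0.13), a difference of 0.35, but inside their random lists at 0.06 with no filter for arrb1 MO and at −0.08 with cyclic loess for arrb2 MO. With both MOs this list lay inside its random lists. The probes of its member krt91 were at 1.39 to 1.65 with arrb1 MO but at 0.11 to 0.22 with both MOs, whereas those of krt18b were lower in both comparisons with control MO.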

How the results depend on the processing

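All 7 alternatives were chosen in advance, and the additive fit afterwards. Under quantile normalization, scaling to the median and cyclic loess, every count of 2-fold genes and every correlation stayed within 1.5 times its value, and so did those under the brightest probe. Of the primary list medians 126 of 136 kept their side of the random range, and of the other list medians 779 of 832. For named genes, judged by the 2-fold threshold since no replicate spread exists, 2254 of 2330 log2 ratios kept their side of 2-fold, 65 lost it, 11 gained it and none changed sign past it; 47 of the 65 were lost under normexp. The number of list medians standing apart ranged from 50 to 60 against 59. The blastula and gastrula median with arrb1 MO ranged from 0.48 to 0.76, and the neuronal differentiation median from −0.76 to −0.32.

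With normexp the counts of 2-fold genes were 298 with arrb1 MO, 96 with arrb2 MO, 900 with both MOs and 261 for arrb1 MO against arrb2 MO. Genes 2-fold the same way numbered 178 for arrb1 MO and 32 for arrb2 MO in pairs that share no array, and 38 against the shared control, and 188 genes departed from additivity by over 1. The blood progenitor median with both MOs was −0.38, hox groups 9 to 13 with both MOs −0.38, and hox groups 1 to 4 for arrb1 MO against arrb2 MO −0.13, all now outside their random lists; the offset of 50 shrinks ratios of dim probes by construction, but the cause of these list changes was not tested. With no filter, which tests more genes, the counts were 1271, 664, 2375 and 1151 in the same order, the same-way counts were 134 for arrb2 MO and 247 against the shared control, and 1464 genes departed from additivity. With only the brighter probes, which tests fewer genes, the counts were 171, 69, 489 and 156, the same-way counts 93, 26 and 24, and 101 genes departed.

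With no filter the blood progenitor median with both MOs was −0.81 and hox groups 9 to 13 with both MOs −0.46, outside their random lists; the interferon median with both MOs turned to −0.059, and the hatching gland median with arrb1 MO from −0.12 to 0.27. With only the brighter probes the blood progenitor median with arrb1 MO was −0.20 and hox groups 9 to 13 with arrb1 MO −0.10, now inside their random lists, hox groups 5 to 8 for arrb1 MO against arrb2 MO was −0.30, now outside, and the interferon median with both MOs was −0.059. With both MOs they also took the blood progenitor median to 0.04 (percentile 49.4) and hox groups 9 to 13 to −0.03 (percentile 38.8), where no filter had moved both the other way. Hox groups 9 to 13 with both MOs stood apart at −0.38 with cyclic loess and at −0.37 with the brightest probe. Ribosomal protein genes with arrb1 MO turned to 0.0099 with scaling to the median, which shifts all genes alike and left its percentile at 0.17, so the list did not turn against other genes; the other causes were not tested.

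Genes past the threshold for arrb1 MO in the additive fit numbered 460, but 275 with quantile normalization, 899 with scaling to the median, 1375 with normexp and 0 with no filter. For arrb2 MO the count of 0 became 71 with normexp. The cause was not tested.

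No paired analysis was possible because the labels pair no samples across groups beyond 1 array each. Leaving out a replicate was not possible with 1 array per group. A block for the slide did not apply, as all 4 arrays were on 1 slide. Signal over background limits the measured genes to 11737, and a gene that was dim on any array enters the counts only as a bound.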

Other observations

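Every test of an explanation in this part was chosen after the result it bears on was seen, and the tests were revised after their values were seen: the bound of the test on eye genes was first loosened and later replaced by one set against the change of rlbp1b, the test on egg genes was then given the same kind of bound, and the tests on neuronal genes were added.

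Several lists lay inside their random lists in each comparison with control MO, though some alternatives moved them. Myeloid genes had medians of 0.06, −0.01 and 0.11 with arrb1 MO, arrb2 MO and both (0.01 with quantile normalization and 0.02 with cyclic loess for arrb2 MO), with −0.18 for both MOs with normexp. Heart field genes had 0.23, 0.08 and 0.23, but stood apart with only the brighter probes at 0.48 (percentile 99.9) for arrb1 MO and 0.45 (percentile 98.1) for both, and turned to −0.10 and −0.15 for arrb2 MO and both with no filter. Presomitic mesoderm and segmentation genes had 0.04, 0.06 and −0.14, and with only the brighter probes 0.14 (percentile 99.1) for arrb2 MO and 0.24 (percentile 92.4) for both. Hatching gland genes had −0.12, 0.07 and 0.30, and with no filter 0.27 (percentile 99.2) for arrb1 MO and 0.32 (percentile 97.9) for both. Neural crest genes, which give rise to pigment and skull cells, had 0.05, −0.06 and 0.14, with 3 of 19 at least 2-fold higher and 5 lower with both MOs, where the median was −0.08 with no filter. Polycomb and YY1 genes had 0.00, −0.08 and 0.04 (−0.02 for arrb1 MO with cyclic loess), and G protein-coupled receptor signalling regulators −0.12, −0.07 and −0.01 (0.08 with scaling to the median and 0.07 with quantile normalization for both MOs). Wnt targets had −0.01, −0.02 and 0.16 (0.05 for arrb1 MO with scaling to the median, 0.01 for arrb2 MO with quantile normalization), Fgf targets −0.07, 0.05 and 0.02 (−0.08 for both MOs with no filter), and Hedgehog targets −0.14, −0.05 and −0.12 (0.05 for both MOs with only the brighter probes).

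A few transcripts, whose levels were singled out after their values were seen, differed on 1 or 2 arrays. The splicing gene smu1a had a log2 level of −0.31 with arrb2 MO and −6.38 with both MOs, and it was not well above background on the other arrays. The level of rlbp1b was −3.89 with control MO, −2.74 with arrb1 MO, 2.33 with arrb2 MO and 1.15 with both MOs, and snu13a was at −0.85 with both MOs against −4.12 with control MO.

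With arrb1 MO, early-stage genes were higher and neuronal genes lower. A scaling difference that depends on brightness is argued against, since it would move the random lists, matched on mean level, in the same way. Under cyclic loess the medians were 0.69 (percentile 100) and −0.74 (percentile 0), which adds little to that matching. With only the brighter probes the neuronal median shrank to −0.32. The pair that shares no array, both MOs against arrb2 MO, had 0.73 (percentile 100) and −0.94 (percentile 0). That pair also differs in total dose, 8 ng against 4 ng. It argues against an error of the control MO or arrb1 MO array alone only if dose does not move these lists, which was not tested. Injection stress in proportion to p53 response genes stays open: the early-stage median exceeded its prediction by 0.43, with a range from resampling of −1.86 to 0.63, and 1180 of 10000 resamples gave no positive p53 median to scale by. A general delay of development, a candidate explanation, cannot be told apart either, as the log2 ratio of 37 hox genes had a correlation with paralog group of −0.17 (Spearman's rho), inside the shuffled range of −0.32 to 0.32, and an effect of arrb1 depletion stays open and untested. The other egg genes, a list added afterwards, had medians of 0.31 (percentile 99.99) with arrb1 MO and 0.57 (percentile 100) with both MOs. They were not set as a test of delay, and 11 of the 27 measured also sit in a fixed list.

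Blood and endothelial progenitor genes were lower with arrb1 MO. In the pair that shares no array, both MOs against arrb2 MO, the median was −0.60 (percentile 0.01). That pair also differs in total dose, 8 ng against 4 ng. It argues against an error of the control MO or arrb1 MO array alone only if dose does not move this list, which was not tested. Fewer blood-forming cells of every kind may be a cause, but primitive erythroid genes had a median of −0.031 (percentile 41.3) with members that went both ways, which decides nothing. An effect of arrb1 depletion, the difference the design names, stays open and untested beside it.

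With arrb2 MO, rlbp1b and the egg-associated genes zp3b, wee2 and rbpms2b were higher, and these 4 were picked, after their values were seen, from the genes higher in both pairs that share no array, so they do not stand for egg genes as a class. RNA of eye tissue that raises eye genes about as much as rlbp1b is argued against: 17 measured of 43 adult eye genes had a median of 0.22 (percentile 99.8; resampled −0.39 to 0.37), below the 6.22 of rlbp1b by more than the full range of the members, from −1.27 to 1.06. With normexp the eye median was −0.08 against 5.39 for rlbp1b, and members spanned 1.08, so this bound was met. With only the brighter probes 1 eye gene was measured, which gives no range to judge by. More maternal RNA of every kind, raising egg genes about as much as those 3, is also argued against: 27 measured of 49 other egg genes had a median of 0.045 (percentile 92.5; resampled −0.03 to 0.14), below the 1.52 of zp3b by more than the full range of the members, from −0.59 to 0.78, and 0 were at least 2-fold higher. That bound was not met with normexp, where rbpms2b was at 0.98, or with no filter, where wee2 was at 0.98, though the highest egg gene was at 0.60 and 0.67 there. Of these egg genes 11 also sit in a fixed list, as do 2 of the eye genes, and 7 are also named genes; a source rich in the 4 genes alone, and an effect of arrb2 depletion, stay open and untested.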
